A study of Schizosaccharomyces pombe with 24 samples.

How the data were processed

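The series holds 24 chromatin immunoprecipitation sequencing (ChIP-seq) libraries from the fission yeast Schizosaccharomyces pombe, made with antibodies against histone H3 dimethylated or trimethylated at lysine 9 (H3K9me2 and H3K9me3). Per the labels' protocols, cells were grown to log phase at 32 °C in YEA, fixed in 1% formaldehyde for 15 min and broken with beads. Libraries were made with the NEBNext Ultra II kit from 1 ng of DNA. The submitters' processing notes name Trimmomatic and BWA without versions. The genome build used for alignment and the read counting are not given in the sources used here.

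The 2 files analysed here are genome annotations of the whole series, which list the start and end of each feature in bases, counted from 1. The authors deposited them as edited copies of public annotations. They hold coordinates and no read count, signal or score per library: the score field was empty in all 58359 rows of one file and all 40352 rows of the other. The first, called the endogenous-site annotation below, carries PomBase as its source and has a tet array feature in the mating-type region of chromosome II. Its features cut by an insertion carry a comment to that effect. The second, called the ectopic-site annotation, was exported from Geneious 7.1.5, per the file headers, and records a replacement on chromosome III. The names of the 2 annotations follow from the position of the reporter feature in each, since no label ties a file to a strain. Read depth, and with it the precision of any ChIP-seq value, is unknown here.

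Libraries were grouped by reporter site, genotype and antibody from their titles. The same deletions written in another order were counted as 1 genotype. Each of the 24 groups held 1 library, and no per-library values were analysed here, so no test between genotypes, antibodies or sites was made. Every result is a description of the annotations and has no replicate error.

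Genes were matched by identifier to the NCBI annotation of the assembly ASM294v3. The shift of each gene start and end against ASM294v3 gave the net length gained or lost upstream of it on its chromosome. Gene starts and ends were counted together. A shift was kept where they held it at least as often as 20 genes with both ends would. It also had to be the commonest in a stretch of neighbouring gene ends. No coordinate was converted: each position is given in the annotation it was read from, or in ASM294v3 where that is named. Positions of the endogenous-site annotation filed under a separate mating-type sequence were read as chromosome II positions, because they fell inside the stretch inserted there. Genes were called protein-coding where they had an mRNA (endogenous-site annotation) or a coding sequence (ectopic-site annotation).

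Genes and repeats were counted where they overlapped a window of 20 kb on each side of the reporter feature, leaving out the reporter. Gene numbers were set beside 10000 random windows (seed 1) of the same width on the same chromosome. GC content was taken from ASM294v3 on both sides of the replaced stretch, with 95% Wilson intervals that cover counting over bases only. The tet operator was searched as TCCCTATCAGTGATAGAGA on either strand. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

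The shift search was tested on simulated data made from the 12403 genes of ASM294v3. It recovered the shifts in 50 of 50 runs with 1 simulated edit and in 50 of 50 runs with 2 edits. The edits lay between the reported bounds in 50 and 49 of these runs. Simulated edits were insertions or deletions away from the chromosome ends. The runs therefore did not cover replacements, or edits as near an end as those at ura4. Gene counts in 200 random windows of chromosome II equalled a direct comparison in 200 windows.

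Before the data were examined, the named genes were fixed as the reporter features, the deleted genes, ura4 and the native ade6, the 3 nearest genes on each side of each reporter, and the members of lists of heterochromatin genes and regions. The lists covered H3K9 methylation, chromodomain and HP1 proteins, RNAi, the SHREC complex, anti-silencing genes, the Mst2 and Set1 complexes, facultative heterochromatin genes, subtelomeric helicase genes, the mating-type region and pericentromeric repeats. A member of the listed genes is not reported here. Other window widths, protein-coding genes alone, matching by name, genes wholly inside the window and operator mismatches were tried as alternatives. Counts without the genes filed under the mating-type sequence, and counts from ASM294v3 at the ectopic site, were added after seeing the data.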

Results

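H3K9me2 and H3K9me3, the histone marks of fission yeast heterochromatin, were profiled by ChIP-seq in 24 libraries around a reporter of 10 tet operators next to ade6+. Tet operators are the binding sites of the tet repressor, and ade6 is an adenine biosynthesis gene whose silencing is read from colony colour. The reporter replaced ura4 at an ectopic site in 14 libraries. In the other 10 libraries it replaced cenH, the repeat element of the silent mating-type region that is related to centromeric repeats, at a site called endogenous in the titles. Each antibody was used once per genotype, in 7 genotypes at the ectopic site and 5 at the endogenous site.

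The 5 genotypes used at both sites were wild type, swi6Δ, swi6Δ mst2Δ, swi6Δ set1Δ and swi6Δ mst2Δ set1Δ. The ectopic site also had clr4Δ and mst2Δ set1Δ. Swi6 is an HP1 protein that binds methylated H3K9, Clr4 is the H3K9 methyltransferase, Mst2 is a histone H3 acetyltransferase and Set1 is the H3K4 methyltransferase. The title of the series places HP1-independent heterochromatin and the role of HP1 proteins in epigenetic memory at its centre. The layout sets each swi6Δ double or triple mutant beside swi6Δ, asking whether loss of Mst2 or Set1 changes H3K9 methylation without Swi6. The mst2Δ set1Δ strain gives the same deletions with Swi6 present, and clr4Δ gives the background without the methyltransferase. H3K9me2 and H3K9me3 levels in these libraries were not analysed here, and no difference between genotypes is stated. With 1 library in each group, such a difference would have no replicate check. The values below describe the genomes in which the reporters were placed.

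At the ectopic site the reporter was annotated as Tetarr-ade6, a feature of 3069 bases on the minus strand of chromosome III, from 115325 to 118393. The annotation recorded 1835 replaced bases, which matched chromosome III of ASM294v3 at 115325 to 117159 and nowhere else on that chromosome. They held the whole ura4 gene (SPCC330.05c), an orotidine phosphate decarboxylase gene on the minus strand at 115589 to 116625 in ASM294v3, with its coding sequence at 115781 to 116575. The reporter thus lengthened the chromosome by 1234 bases, and genes from there to the native ade6 locus were shifted by the same 1234 bases. No ura4 gene was annotated in this file. The replaced bases had no tet operator at up to 2 mismatches, and the closest stretch differed from the operator at 7 of 19 positions. These bases were the ones removed, so the search says nothing about the operators of the reporter. The sequence of the inserted reporter itself was not analysed here.

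The nearest gene to the left of the ectopic reporter was tam14 (114921 to 115256, plus strand), 68 bases away. A glycine tRNA gene, SPCTRNAGLY.10 (113716 to 113786), followed at 1538 bases and mug135 (112050 to 113477) at 1847 bases. To the right lay new25 (118812 to 119081) at 418 bases, SPCC330.06c (119456 to 120236) at 1062 bases and the non-coding gene SPNCRNA.1110 (120204 to 121196) at 1810 bases. All of these except tam14 were on the minus strand. The 3 long terminal repeats within 20 kb, remnants of retrotransposons, all lay to the left, at 594, 3764 and 6461 bases.

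At the endogenous site the tet array was annotated as 9xtetoura4, a feature of 1881 bases on the minus strand of chromosome II, from 2135068 to 2136948. The labels name 10 operators and ade6+ for this site, so the annotated name differed from them in both the operator number and the marker. It lay between the mating-type genes mat2-Pc (2132562 to 2132961), 2106 bases to the left, and mat3 (2139388 to 2139933), 2439 bases to the right. These silent cassettes are the donors of mating-type switching. The next genes to the left were the non-coding gene SPNCRNA.5505 (2128683 to 2129020) at 6047 bases and rpp202 (2127990 to 2128467), a ribosomal protein gene, at 6600 bases. To the right, 3 bases of the non-coding gene SPNCRNA.391 remained at 2143661 to 2143663, 6712 bases away, followed by SPNCRNA.1489 (2144068 to 2146079) at 7119 bases. The nearest genes annotated as protein-coding were rpp202 on the left and emc3 (2144858 to 2146287), 7909 bases away, on the right. The active mating-type gene mat1-Mc (2114482 to 2115027) lay 20040 bases to the left and the centromere of chromosome II 490320 bases to the left.

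Genes to the right of the endogenous reporter were shifted by 6539 bases against ASM294v3. The replaced stretch ended at 2137121 in ASM294v3 and began between 2129021 and 2129803, taking the first gene whose identifier is missing as inside it. That gave 7319 to 8101 replaced bases and 13858 to 14640 inserted bases. The 6 gene identifiers of ASM294v3 missing from this stretch were those of mat3-Mi, mat3-Mc and the non-coding genes SPNCRNA.389, SPNCRNA.390, SPNCRNA.5506 and SPNCRNA.5507. The feature named mat3 in the inserted stretch had the length of mat3-Mc, 546 bases. The inserted stretch also held mat2-Pc, whereas no mat2 gene was among the missing identifiers. The 6539 bases are thus the net change over the whole stretch and not that of the reporter in place of cenH. Neither annotation had a feature named cenH, IR-L or IR-R.

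**Figure D1:**
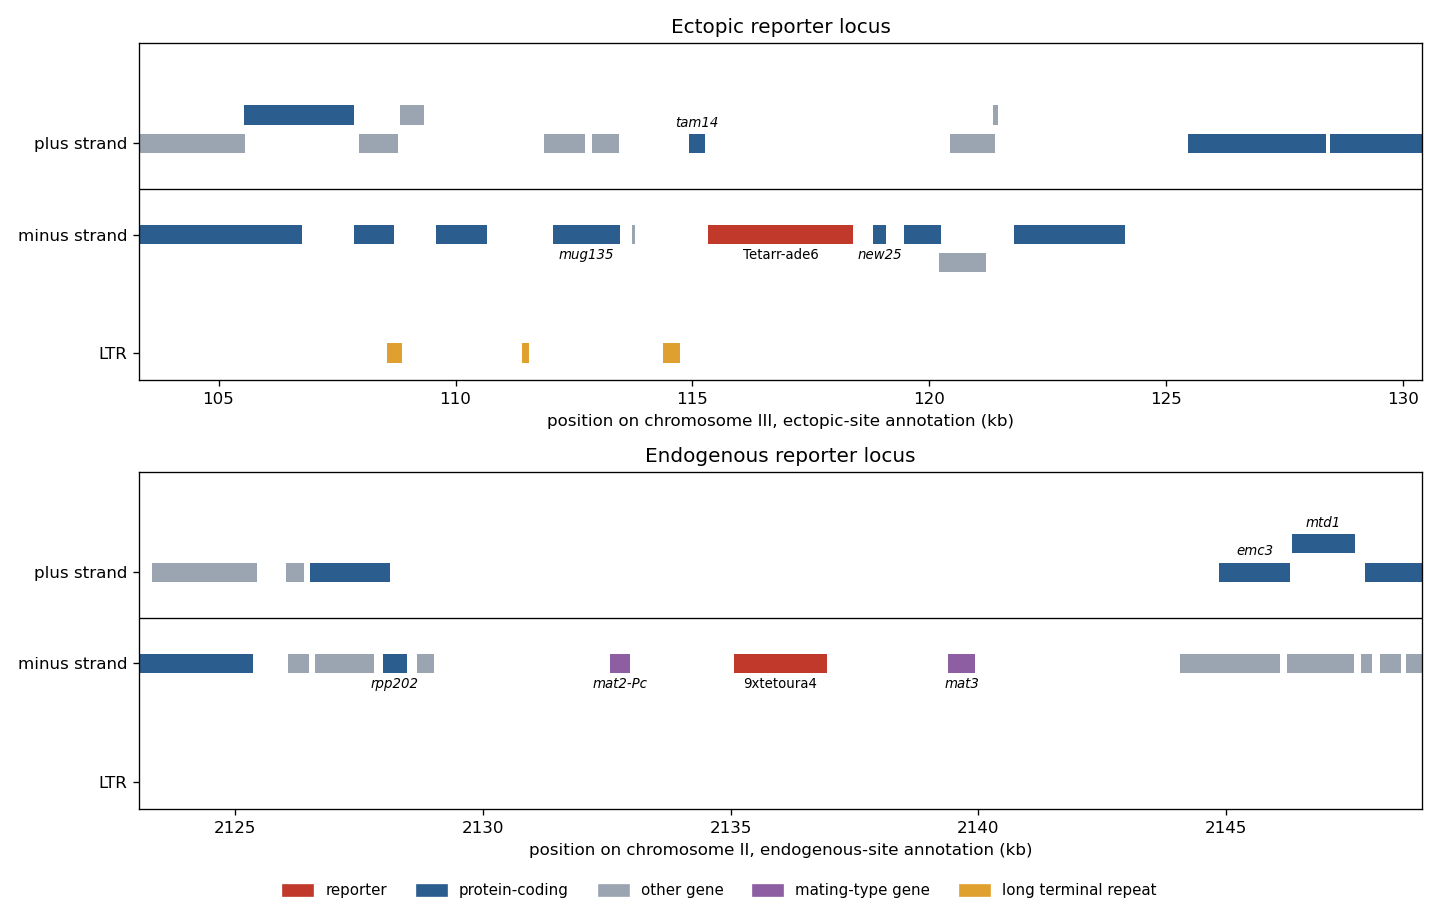
Genes around the ectopic reporter on chromosome III (top) and the endogenous reporter on chromosome II (bottom), with position in kb on the horizontal axis of each annotation and bars for features on the plus strand, the minus strand and, lowest, long terminal repeats (LTR). The ectopic reporter sits 68 bases from tam14 and 418 bases from new25, and the endogenous reporter sits 2106 bases from mat2-Pc and 2439 bases from mat3.

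Within 20 kb the ectopic reporter had 29 genes, 19 of them protein-coding. The median of random windows on chromosome III was 24 genes, and 90.9% of the windows held as many genes as the reporter window or fewer. The endogenous reporter had 34 genes, 13 of them protein-coding, against a median of 44 genes in random windows on chromosome II. Of these windows 3.59% held as many or fewer. The inserted 13858 to 14640 bases in this window carried 3 annotated features, the reporter among them. Without the 2 mating-type genes, 32 genes lay in the rest of the window. No share was taken for that rest alone, so 3.59% does not show that the flanks were poor in genes. For protein-coding genes alone the shares were 77.2% at the ectopic site and 8.17% at the endogenous site. The endogenous protein-coding counts leave out mat2-Pc and mat3, which had no annotated mRNA, although mat3-Mc is protein-coding in ASM294v3. The mat3-Mi gene, also protein-coding in ASM294v3, is missing from this annotation and from these counts. With 40 kb on each side the endogenous share was 15.7% for all genes and 52.6% for protein-coding genes. Total gene numbers were not comparable between the sites, because the ectopic-site annotation listed fewer non-coding genes. Besides mat2-Pc and mat3, the endogenous window held no annotated repeat within 20 kb, and the ectopic window held 3. Repeat numbers were not comparable between the sites either. The annotations used different repeat feature types, and no repeat was annotated in the inserted stretch. GC content was 35.6% at the ectopic site (95% Wilson interval 35.1 to 36.0%) and 35.6% at the endogenous site (35.1 to 36.0%) in the 20 kb on each side, against 36.2% over chromosome III and 35.9% over chromosome II.

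The marker genes differed between the annotations. The native ade6 gene (SPCC1322.13, 1755 bases) was present in the endogenous-site annotation at 1314474 to 1316228 on chromosome III and absent from the ectopic-site annotation. There, 1828 bases had been removed between 1316006 and 1318374 of ASM294v3. A single removal of that length takes at least 1449 of the 1659 coding bases of ade6 (87.3%), wherever it lies between those bounds. The endogenous-site annotation lacked ura4 and was shorter by 1807 bases between 115324 and 117577 of ASM294v3, a removal that takes all 795 coding bases of ura4. Neither annotation followed a mutant genotype: clr4 (II, 453996 to 458410), swi6 (I, 1702406 to 1704098), mst2 (I, 2363499 to 2366934) and set1 (III, 410486 to 414140) were all present in the endogenous-site annotation. They had coding sequences of 1473, 987, 1224 and 2763 bases, the same lengths as in the ectopic-site annotation.

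**Figure D2:**
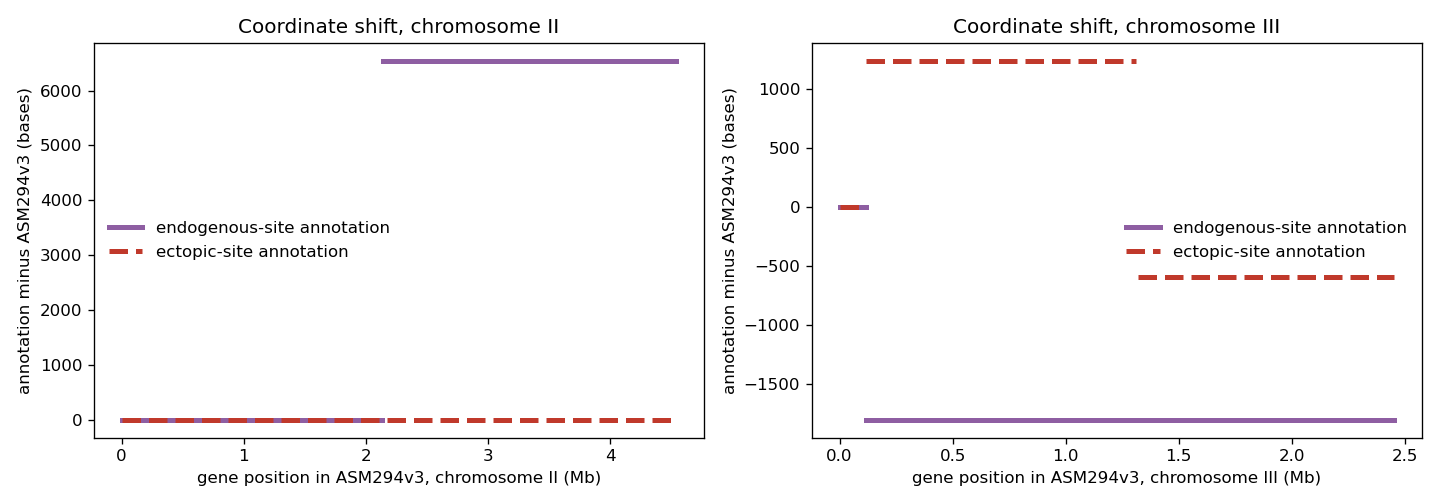
Coordinate shift of genes in each annotation against ASM294v3 (bases, vertical axis) along chromosomes II and III (gene position in Mb, horizontal axis), with a solid line for the endogenous-site and a dashed line for the ectopic-site annotation. Chromosome II steps up by 6539 bases in the endogenous-site annotation alone, and chromosome III steps to 1234 and then -594 bases in the ectopic-site annotation and to -1807 bases in the endogenous-site annotation.

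The 2 annotations shared 6779 gene identifiers, of 6951 genes in the ectopic-site and 12633 in the endogenous-site annotation. Among protein-coding genes 5095 were shared, with 18 called protein-coding only in the endogenous-site and 25 only in the ectopic-site annotation. In the endogenous-site annotation 99.96% of the 5519 matched genes of chromosome I had both ends at their ASM294v3 positions. In the ectopic-site annotation this held for 26.6% of 2974 genes on chromosome I, where most genes differed at an end although the commonest shift was 0. Coding starts, taken as the lowest coding coordinate on either strand, were therefore used to compare the files. They differed by the edited lengths for 1865 of the 5095 shared protein-coding genes (36.6%): 999 on chromosome II by 6539 bases, 435 on chromosome III by 3041 bases and 431 on chromosome III by 1213 bases.

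All 41 listed heterochromatin genes reported here were in both annotations with the same coding length, and the coding start of 16 differed between them. Of 5 genes for H3K9 methylation, 3 differed: raf2 by 3041 bases, rik1 by 1213 bases and stc1 by 6539 bases. The coding starts of clr4 and cul4 were the same. Among 9 RNAi genes 4 differed, with ago1, the Argonaute gene, at 3041 bases and dcr1, the Dicer gene, hrr1 and cid12 at 1213 bases. Of the 3 chromodomain and HP1 genes chp2 differed by 6539 bases, and swi6 and chp1 did not. Of 5 genes of SHREC, a histone deacetylase complex, clr1 and chp2 differed by 6539 bases. Of the 3 anti-silencing genes, set1 differed by 3041 bases and epe1, which encodes a JmjC-domain protein that opposes heterochromatin spreading, by 1213 bases. Among 7 Mst2 complex genes nto1 and ptf2 differed by 6539 bases, and among 8 Set1 complex genes set1, ash2 and sdc1 differed, by 3041, 6539 and 1213 bases. None of the 3 facultative heterochromatin genes mei4, ssm4 and mcp7 differed. Of the subtelomeric helicase genes, tlh2 at the right end of chromosome II differed by 6539 bases and tlh1 on chromosome I did not.

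Pericentromeric repeats, where H3K9 methylation is found in wild-type cells, were annotated by type in the endogenous-site annotation. By feature type it listed 11 dg and 16 dh repeats, 6 inner repeat regions and 3 central cores. No feature carried dg, dh, imr, cnt or otr as its name in either annotation. Chromosome III held 7 of the dg and 10 of the dh repeats, and its centromere (1069097 to 1135196) spanned 66100 bases. The centromeres of chromosomes I (3753687 to 3789421) and II (1602418 to 1644747) spanned 35735 and 42330 bases.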

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

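Of 42 alternatives, 23 kept their result, 19 moved it and 0 reversed it. Counts, lengths and distances carry no direction, so a reversal was not possible for them. Each alternative changed a single setting. Combined settings, such as protein-coding genes in 40 kb windows, were not among the 42. A count was taken as kept within 1.5 times its value, a share or GC content within its 95% Wilson interval, and a length or distance where it was equal. Kept counts include genes shared, 6779 against 5095 when protein-coding. They also include the operators in the replaced ura4 bases, 0 at up to 1 and up to 2 mismatches, where none had reason to occur. No paired analysis was possible because no per-library values were analysed here and no result came from a test. The net changes in length (1234 and 6539 bases) were the same from gene ends, from protein-coding genes and by name. With 10 kb windows the gene numbers were 19 at the ectopic and 15 at the endogenous site, and with 40 kb 60 and 78. Genes annotated as protein-coding numbered 19 and 13, the latter without mat2-Pc and mat3. The share of random windows with as many genes or fewer went at the ectopic site to 97.5% (10 kb), 99.97% (40 kb) and 77.2% (protein-coding), and at the endogenous site to 2.18%, 15.7% and 8.17%. For protein-coding genes the share at the endogenous site was 3.79% in 10 kb and 52.6% in 40 kb, and at the ectopic site 66.5% and 95.6%. These shares include windows with an equal number. In 40 kb at the endogenous site the count equalled the median of 35, and 40.46% of windows held fewer. In 10 kb at the ectopic site it equalled the median of 10, and 44.56% held fewer. The nearest genes annotated as protein-coding lay 6600 bases to the left of the endogenous reporter and 7909 to the right. Without the genes filed under the mating-type sequence, a choice made after seeing the data, the nearest lay at 6047 and 6712 bases. Mating-type genes and repeats at the endogenous site numbered 5 in 40 kb windows, which add mat1-Mi and mat1-Mc of the active mat1 locus and 1 long terminal repeat. GC content at the ectopic site was 34.4% in 10 kb windows. Matched by name, the annotations shared 2981 genes. Wider windows and fewer gene types change these counts by construction, and the cause was not tested for the GC value. Genes of ASM294v3, added after seeing the data, numbered 43 around the ectopic site, against 29. Read depth is unknown and limits nothing reported here.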

Other observations

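All tests in this part were chosen after the values were seen, and no biological explanation was tested, since the annotations carry no group of the study.

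The mat3 gene in the endogenous-site annotation had the 546 bases of mat3-Mc in ASM294v3 and lay exactly 6539 bases from it (2132849 to 2133394 in ASM294v3), the shift of the genes to the right of the insertion. Its spacing to those genes was thus that of the reference, whereas its strand was minus in the annotation and plus in ASM294v3. The 1807 bases missing around ura4 in the same annotation were 4 more than the 1803 bases between the outer HindIII sites of the replaced ura4 stretch (115345 and 117148 in ASM294v3). This was the closest of the fragments compared: an inner site at 117103 gave fragments of 1758 and 45 bases, 49 and 1762 fewer than were missing. Only sites of the replaced stretch were compared, although the removal could reach 117577. How cut ends would have been joined is unknown. The difference of 4 bases therefore cannot exclude a removal between the outer sites, nor does it show one.

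The endogenous reporter was named for 9 operators and ura4, against 10 operators and ade6+ in the labels. If its 1881 bases held the whole annotated ade6 gene, 126 bases would be left, fewer than the 171 that 9 operators of 19 bases need without spacers. This argues against a complete ade6 gene with its annotated untranslated ends. With the ura4 gene (1037 bases) 844 bases would be left, enough for the operators, so a feature carried over from a ura4 reporter is a candidate explanation. The ade6 coding sequence alone would leave 222 bases, also enough, so a shorter ade6 marker stays open, and lengths cannot tell it from ura4. The ectopic reporter would keep 1314 bases beside a complete ade6 gene. If the annotated feature is not the construct in the strains, H3K9 methylation read over it may be placed on sequence the strains do not carry.

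In the endogenous-site annotation some features carry coordinates in their identifiers. Beyond the edits on chromosomes II and III, 40 of 40 such features of other types had moved by the edited length at both ends, away from their identifiers, whereas 9 of 9 features of the type called region stood at the coordinates in theirs. Region features left wholly at their earlier coordinates are argued against by 2 of them on chromosome III, at 1435178 to 1434842 and 814799 to 813089, whose start lies beyond their end. A candidate explanation is that the end moved with the edit and the start did not, with the identifier holding the edited end: 4 of the 9 starts fell on a feature start of the unedited genome as written and 0 with the shift taken off, while 0 ends fell on a feature end as written and 2 with the shift taken off. Signal averaged over the 6 such features of chromosome II as written may then cover 6539 bases too many.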
